A study of Capsella orientalis and Capsella grandiflora with 23 samples.

How the data were processed

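The series holds 23 samples of Capsella grandiflora (Cg) and Capsella orientalis (Co): leaf genomic DNA (4 Cg, 2 Co), bisulfite-treated leaf DNA (1 Cg, 2 Co) and endosperm RNA (6 Cg, 8 Co, counting repeat sequencing runs). The 4 tables used here hold allele-specific RNA values only. Values of the leaf genomic and bisulfite samples were not analysed here.

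Per the file headers, the deposited tables list SNP positions, with a maternal and a paternal allele count in each of 2 cross directions, the exon and gene interval of the SNP, and the authors' summaries per gene. The allele columns are whole-number read counts at a single position, and the total column is their count summed over the SNPs of a gene. A read that spans several SNPs is counted at each of them, so summed counts exceed the number of molecules. The deposited totals equalled the summed allele counts for 100% of SNPs with a total. The authors' deposited ratio equalled maternal / (maternal + 2 x paternal) of the gene sums for 100% of values, within 1e-06. The deposited p-values carry the name of a chi-square test per gene, per the file headers. Trimmomatic, Bismark and Bowtie2 are named, without versions or roles, per the submitters' processing notes. The RNA aligner, SNP caller, genome build, annotation and the treatment of repeat runs are not given in the sources used here. A further 18 columns of each deposited file were not used.

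The column names state the parent of each allele and a direction number, but no sample. Which accession was the mother in a direction, and which Cg accessions a table covers, was therefore left open, and no column was tied to a named sample. Species was read from the names of the tables alone, together with the series design of 2 reciprocal replicates per species. The tables of a species are called pair 1 and pair 2 here, and their directions 1 and 2, after the numbers in the table names and columns. The 2 Co tables shared 16619 SNPs (95.6% of those in pair 2), and the 2 Cg tables shared 9647 (8.43% of those in pair 1). The tests below treat the 4 directions of a species as its libraries. Per the labels the Co libraries are replicates of crosses of the same 2 accessions. Nothing says how their plants were kept apart, so the spread between these libraries may be partly technical. The restriction that no library could be matched to a named sample applies to each test.

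Gene counts were sums over the SNPs assigned to the gene interval listed first. Genes with at least 20 informative reads in every direction were tested. Each direction gave a maternal and a paternal column (8 per species). edgeR 4.0.16 (R 4.3.3) fitted a quasi-likelihood model with the library as a block, the accession of the allele within each pair, and the parent of origin. The block was part of the design because both alleles were counted in 1 library. The maternal columns carried an offset for the 2 to 1 maternal dosage of endosperm, so a log2 deviation of 0 means a maternal share equal to that dosage, and positive values are maternal. The fit of a species left 1 residual degree of freedom per gene, and the spread was moderated across genes. Each accession term absorbs the difference between the 2 directions of its pair. A gene's own spread is thus that of 2 pair means, not of 4 independent directions. In Co the p-values followed almost wholly a spread pooled over genes, so the Co test was more lenient. A deviation of 4.60 ± 1.08 had an unadjusted edgeR p of 2.33e-05 in Co, and one of -1.41 ± 0.24 had 0.000257 in Cg. The difference between species was the interaction of parent and species in genes tested in both. The SE printed with a deviation is its absolute value divided by the square root of the F statistic. Where 1 parent had no or few reads, the size of a deviation depends on the small prior count that edgeR adds. Rankings by deviation depend on it too. Adjusted p-values are Benjamini-Hochberg values, called at 0.05. Overlaps were tested with Fisher's exact test, two-sided, with scipy 1.17.1.

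Strictly maternal genes were called genes with a maternal share of at least 0.85 in every direction, and strictly paternal genes were called genes with a paternal share of at least 0.5 in every direction. Counts are also given for called genes that lay on the same side of the dosage in all 4 directions. Leading with that count was decided after the data were seen, although the rule for named genes contained it beforehand. On data simulated from the real totals with accession effects, the Cg fit (4404 genes) recovered 96% and 100% of genes at deviations of -4 and 4, and 82% and 64% at -2 and 2, under the larger noise (SD 0.6). The Co fit (1356 genes) recovered 100% at -4 and 4, and 88% and 76% at -2 and 2. False calls made up 12.7% of Cg calls and 6.98% of Co calls under the smaller noise (SD 0.3), above the nominal level, and 2.21% and 1.82% among calls on the same side in all 4 directions. The simulation centred unchanged genes at the dosage in every direction. In the real data the median share over genes was 54.3% in direction 1 of Cg pair 2, so these rates may not hold there.

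The named genes were fixed before the data were examined: per species, the maternal and paternal genes with the largest deviation among called genes on the same side in every direction with a mean of at least 50 reads, then genes called the same way in both species by mean deviation, then genes with the smallest p for the species difference. The files pair the gene intervals with no gene names and no genome came with them, so at most 2 genes of each set are named, by coordinates. For the same reason the 11 fixed gene lists, which hold Arabidopsis identifiers and include markers of seed coat, embryo and endosperm, were matched to no gene and tested nowhere. A check for tissue other than endosperm by marker genes was thus not made. Seed coat is maternal tissue, so maternal bias from seed coat RNA in a sample cannot be told apart from imprinting.

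Total informative counts per direction ranged from 208132 to 9508567. Shares of single directions carry 95% Wilson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. Where a read spanned several SNPs of a gene it was counted at each, so these intervals, and the limits given next, are then too narrow. A share of 0% or 100% is given with the limit that a count of 0 allows (3 counts of the total).

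The alternatives fixed before the data were examined were DESeq2 1.42.0, a null at each direction's median log ratio, a null at 1 to 1, TMM normalization, minimum counts of 10 and 50 or none, the SNP with most reads per gene, models without the accession term or the block, removal of SNPs where one accession held under 5% of reads in both directions, an exact binomial test, other strict thresholds, and leaving out each direction. Leaving out a direction also removed the accession term of its pair, so a call lost this way cannot be put down to that direction alone. Restriction to SNPs in annotated exons, restriction to SNPs listed in both directions, overlaps of calls on the same side in every direction, and the balance of maternal and paternal calls were added after the data were seen.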

Results

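Genomic imprinting is the expression of a gene mainly from the allele of one parent, and in flowering plants it is found chiefly in endosperm, the tissue that nourishes the embryo and that carries 2 maternal genomes and 1 paternal genome. The series measured it in reciprocal crosses within C. grandiflora (Cg), an outcrossing relative of Arabidopsis, and within C. orientalis (Co), a self-fertilising one. Endosperm RNA came from 300 to 500 seeds per sample, 6 days after pollination. Reads over SNPs between the parental accessions were assigned to the mother or the father. Cg was crossed among 4 accessions in 2 reciprocal pairs, and Co between 2 accessions in 2 replicates of 1 reciprocal pair, which gives 4 cross directions per species.

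Depth differed widely between these directions. Cg pair 1 held 9508567 and 9378895 informative counts in directions 1 and 2, and Cg pair 2 held 601511 and 1099158. Co pair 1 held 520680 and 208132, and Co pair 2 held 570062 and 596843. Of 22736 Cg genes with an informative SNP, 4404 had at least 20 reads in every direction and were tested, against 1356 of 8844 in Co. Genes are identified by their interval on the scaffolds of the authors' assembly, whose build is not given in the sources used here.

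The first question was whether total expression followed the 2 to 1 dosage of the parental genomes. Summed over all informative reads, the maternal share lay below that dosage in all 8 directions, while its median over genes lay above it in 3 Co directions. In Cg it was 63.9% (95% Wilson interval 63.9% to 63.9%) and 65.6% (65.6% to 65.7%) in pair 1, and 52.7% (52.5% to 52.8%) and 61.3% (61.2% to 61.4%) in pair 2. In Co it was 60.7% (60.6% to 60.8%) and 64.3% (64.1% to 64.5%) in pair 1, and 66.3% (66.2% to 66.5%) and 64.8% (64.7% to 65.0%) in pair 2. SNPs in annotated exons gave shares of 64.9%, 66.1%, 52.0% and 65.0% in Cg, and 61.5%, 66.4%, 66.7% and 66.8% in Co. SNPs outside annotated exons gave 53.1%, 60.6%, 58.2% and 47.4% in Cg, and 57.0%, 45.5%, 63.1% and 46.3% in Co. They were 38.1% to 44.9% of the SNPs of a table. The median over genes was 65.9%, 66.7%, 54.3% and 61.0% in Cg, and 61.0%, 68.1%, 68.1% and 68.2% in Co. No test was made across the directions, which are given singly.

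**Figure D1:**
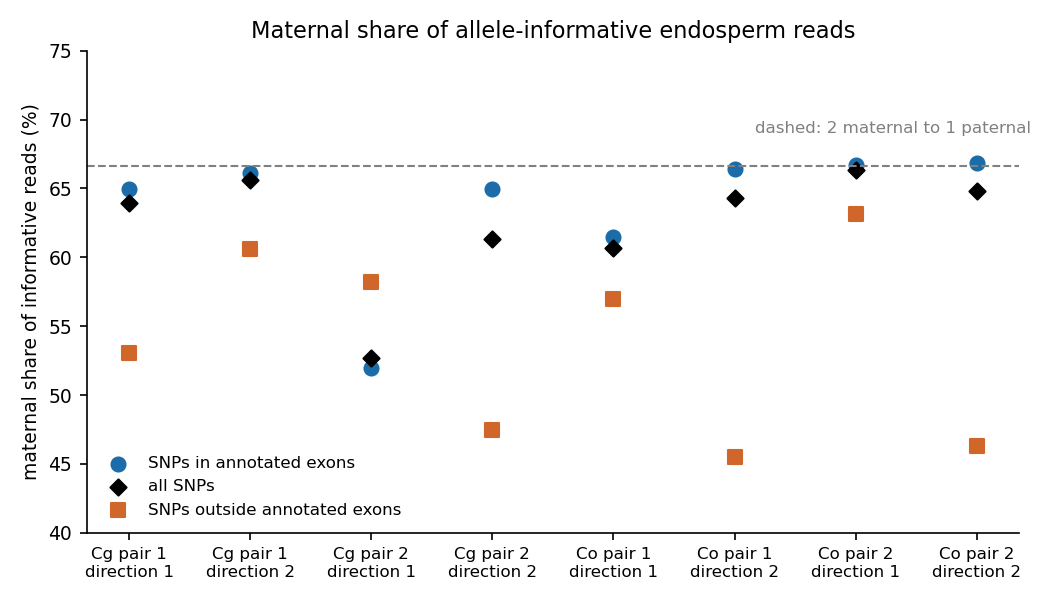
Maternal share of allele-informative endosperm reads (percent, y axis, from 40 to 75) in each of the 4 cross directions of Cg and Co, for all SNPs (black), SNPs in annotated exons (blue) and SNPs outside them (orange). The dashed line marks the 2 to 1 dosage. Direction 1 of Cg pair 2 had an exonic share of 52.0%, and exonic shares of the other 7 directions lay between 61.5% and 66.8%.

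The second question was which genes deviated from the dosage in Cg. Parental bias in Cg fell mostly on the paternal side: 53 genes were paternally and 18 maternally biased on the same side in all 4 directions, out of 4404 tested. Of all tested genes, called or not, 335 lay below and 81 above the dosage in every direction, so the same-side rule itself favoured paternal genes. With the null and the sides set at each direction's median, which by itself brings all tested genes near balance, 39 paternal and 20 maternal genes were called on the same side. The paternal genes had a median log2 deviation of -3.02 and the maternal genes of 3.19. A gene on scaffold 8 (8166727 to 8168509, plus strand) was expressed almost wholly from the father, with a log2 deviation of -7.37 ± 0.47 (SE, n = 4 directions in 2 pairs, edgeR adjusted p = 0.000177). Its maternal share was 1.84% (1.24% to 2.73%) and 0.781% (0.379% to 1.60%) in pair 1. In pair 2 it was 0 of 116 reads, which allows up to 2.59%, and 10.8% (5.81% to 19.3%) of 83 reads. These values came from 1 exonic SNP in pair 1 and 2 in pair 2. Another on scaffold 4 (1940495 to 1941686, plus strand) deviated by -7.16 ± 0.54 (edgeR adjusted p = 0.000331), with maternal shares of 0.941% and 1.94% in pair 1. In pair 2 its maternal share was 0 of 25 reads, which allows up to 12%, and 33.3% (17.2% to 54.6%) of 21 reads. It held 9 and 4 SNPs in the pairs, all in annotated exons.

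On the maternal side of Cg, a gene on scaffold 5 (12789380 to 12789916, minus strand) deviated by 7.98 ± 1.39 (SE, n = 4 directions in 2 pairs, edgeR adjusted p = 0.0276). All reads were maternal in 3 directions, with 96, 77 and 20 reads that allow maternal shares down to 96.9%, 96.1% and 85%, and 82.8% (65.5% to 92.4%) of 29 reads in the other. The gene on scaffold 1 at 4155070 to 4156370 (plus strand) deviated by 6.46 ± 1.08 (edgeR adjusted p = 0.0155), with maternal shares of 99.7%, 95.7% and 97.1% in 3 directions and all of 455 reads in direction 2 of pair 1, which allows down to 99.3%. Its signal rested on 1 SNP in pair 1 and 2 SNPs in pair 2, and that of the scaffold 5 gene on 1 and 5 exonic SNPs. The scaffold 5 call was lost when any 1 direction was left out (deviation 4.40 to 8.59, edgeR adjusted p from 0.0964 to 0.996). Its deviation stayed at 7.98 to 8.00 with the median null (adjusted p = 0.0614), TMM (0.0585), exonic SNPs (0.0994) and SNPs in both directions (0.0527), where only the adjusted p moved past 0.05.

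In all, edgeR called 87 Cg genes, 24 maternal and 63 paternal, and 16 of them did not lie on the same side in every direction. Among all tested genes 9.45% lay on 1 side in all 4 directions, against 12.5% for independent coin flips. The Cg calls depended on the accession term: without it 0 genes were called (143 at an unadjusted p under 0.05; DESeq2 with the term called 143), and 0 without the library block. Leaving out direction 2 of pair 1, or either direction of pair 2, also left 0 calls, and leaving out direction 1 of pair 1 left 52, 42 of which were among the 71. Each of these fits also lacked the accession term of the pair concerned, so the losses cannot be put down to the direction alone.

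The same question in Co gave a more even split, with 30 maternally and 27 paternally biased genes on the same side in all 4 directions, out of 1356 tested. Of all tested genes, called or not, 65 lay below and 103 above the dosage in every direction. The split depended on the setting: maternal and paternal genes numbered 20 and 7 with DESeq2, 31 and 14 with exonic SNPs, 16 and 9 with at least 50 reads, and 49 and 88 over all calls. Maternal deviations were the larger, with a median of 2.66 against -1.21 for paternal genes. A gene on scaffold 5 (6015323 to 6016372, plus strand) gave only maternal reads in all 4 directions, 292 counts over 3 exonic SNPs. Its log2 deviation was 8.78 ± 1.13 (SE, n = 4 directions in 2 pairs, edgeR adjusted p = 1.41e-12). With no paternal read, the size of this deviation was set by the prior count of edgeR and by depth. The gene's 51, 36, 79 and 126 reads allow maternal shares down to 94.1%, 91.7%, 96.2% and 97.6%. Scaffold 1 held another maternal gene (9766051 to 9767358, minus strand), which deviated by 7.53 ± 0.87 (edgeR adjusted p = 1.99e-15). Its maternal share was 81.7% (72.0% to 88.6%) in direction 1 of pair 1 and 99.3% in direction 1 of pair 2, and all of 58 and of 171 reads were maternal in the others, which allows down to 94.8% and 98.2%. These reads covered 1 exonic SNP. The scaffold 5 gene deviated by 7.50 with DESeq2, where its call was lost (adjusted p = 0.335), and by 8.41 to 8.97 with a direction left out. The scaffold 1 gene deviated by 4.16 to 8.66 with a direction left out, and had an edgeR adjusted p of 0.00807 when only genes with at least 50 reads were fitted. Both calls held without direction 1 of pair 2 (adjusted p = 0.0421) and were lost without any other direction (0.221 to 0.790).

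On the paternal side of Co, a gene on scaffold 7 (11097355 to 11102864, minus strand) deviated by -7.27 ± 0.77 (SE, n = 4 directions in 2 pairs, edgeR adjusted p = 2.54e-18). Its maternal share was 4.0% (0.710% to 19.5%) of 25 reads and 5.88% (2.72% to 12.2%) of 102 reads in direction 1 of pair 1 and direction 2 of pair 2, and 0 of 30 and of 71 reads in the others, which allow up to 10% and 4.23%. Another paternal gene, on scaffold 8 (8879381 to 8883328, plus strand), deviated by -3.76 ± 0.22 (edgeR adjusted p = 1.82e-55), with maternal shares of 21.8% (17.0% to 27.6%), 11.9% (7.84% to 17.7%), 8.40% (6.07% to 11.5%) and 12.8% (10.3% to 15.7%). The scaffold 7 gene rested on 1 exonic SNP in Co, and the scaffold 8 gene on 8 SNPs, 4 of them in annotated exons. The small p of the scaffold 8 gene depended on the genes and SNPs fitted, with edgeR adjusted p = 0.00162 at a minimum of 50 reads and 1.98e-10 with exonic SNPs. Without direction 1 of pair 2 it was 0.0335, and without another direction 0.128 to 0.708, with deviations of -4.03 to -3.50.

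In all, edgeR called 137 Co genes, 49 maternal and 88 paternal, of which 80 did not lie on the same side in every direction. Since the Co test was the more lenient, this number does not compare with that of Cg. Accession differences were strong in Co: across genes, which are not independent replicates, maternal shares of direction 1 correlated between pairs (r = 0.72, rho = 0.55), as did those of direction 2 (r = 0.86, rho = 0.65), and opposite directions correlated negatively (r from -0.53 to -0.46). Without the accession term 0 Co genes were called (71 at an unadjusted p under 0.05; DESeq2 with the term called 46), and without the block 22. Leaving out either direction of pair 1 or direction 2 of pair 2 left 0 calls, and leaving out direction 1 of pair 2 left 44. Here too the accession term of the pair concerned was dropped. On the same side in every direction, DESeq2 called 20 maternal and 7 paternal genes.

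**Figure D2:**
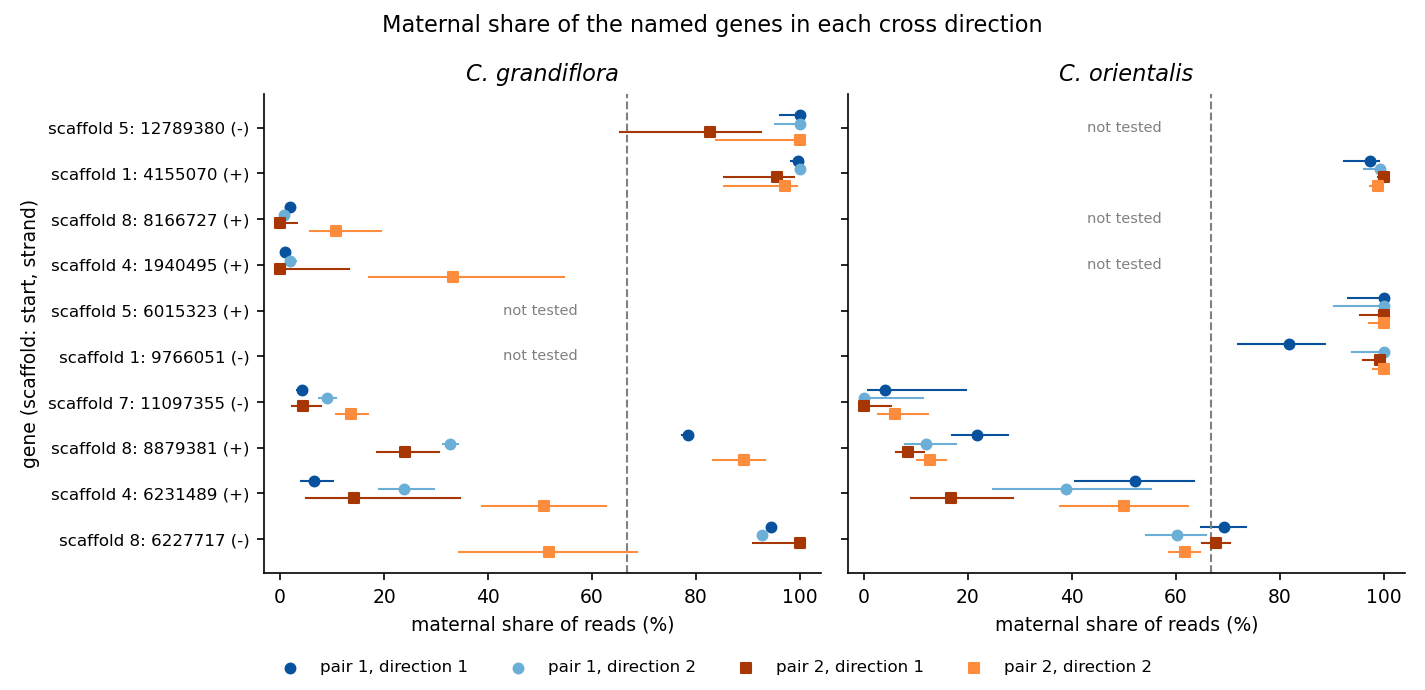
Maternal share of reads (percent, x axis) of the 10 named genes (y axis, scaffold and start) in Cg (left) and Co (right). Points are single cross directions, bars are 95% Wilson intervals, and the dashed line marks the 2 to 1 dosage. The gene at 4155070 on scaffold 1 lay above 95% in all 8 directions, and the gene at 11097355 on scaffold 7 lay below 14% in all 8.

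A stricter size rule asked which called genes passed fixed shares in every direction, a maternal share of at least 0.85 or a paternal share of at least 0.5, the latter being a moderate bias. In Cg 47 genes met it, 9 strictly maternal and 38 strictly paternal. In Co 17 genes met it, 15 strictly maternal and 2 strictly paternal, the latter being the named genes on scaffolds 7 and 8. Without the test, 10 and 47 Cg genes passed these shares, against 15 and 2 in Co. With at least 50 reads per direction the strict counts were 24 in Cg and 9 in Co. As with all calls, leaving out direction 2 of Cg pair 1, either direction of Cg pair 2, either direction of Co pair 1 or direction 2 of Co pair 2 left 0.

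A further question was whether parentally biased genes were shared between the species. Among 584 genes tested in both, paternally biased genes overlapped more than independent lists would: 6 genes were called paternal in both, out of 11 in Cg and 42 in Co, against 0.791 expected (odds ratio 17.9, Fisher's exact p = 3.43e-05, two-sided). These included the genes at 7693692 and 10071410 on scaffold 2, whose Co maternal shares alternated with the direction. In fractions they were 0.883, 0, 1 and 0 for the former, and 0.036, 0.894, 0.008 and 0.881 for the latter. Of calls on the same side in every direction, which leave these genes out, 4 were shared out of 7 and 14 (odds ratio 75.6, Fisher's exact p = 7.01e-06). The gene at 11097355 to 11102864 on scaffold 7 led them, with maternal shares in Cg of 4.16% (3.30% to 5.24%), 8.99% (7.52% to 10.7%), 4.37% (2.39% to 7.85%) and 13.6% (10.8% to 16.9%), a Cg deviation of -4.76 ± 0.30 and edgeR adjusted p = 0.000177. The next shared gene with a mean of at least 50 reads in each species lay on scaffold 4 (6231489 to 6235749, plus strand), with deviations of -3.14 ± 0.61 in Cg (edgeR adjusted p = 0.0321) and -1.70 ± 0.50 in Co (adjusted p = 0.00946). Its maternal shares were 6.51%, 23.9%, 14.3% and 50.8% in Cg and 52.2%, 38.9%, 16.7% and 50% in Co. Its call was lost in both species when any 1 direction was left out, with deviations of -3.70 to -2.42 in Cg (edgeR adjusted p from 0.278 to 0.680) and -1.98 to -1.17 in Co (0.289 to 0.860). The deviation was close to that of all data, and the call lost, in Cg with the median null (-2.98, adjusted p = 0.110) and TMM (-2.91, 0.123) and in Co with DESeq2 (-1.71, 0.160).

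Of maternally biased genes, 1 was shared, out of 3 in Cg and 19 in Co, and over all calls this overlap did not pass the test (odds ratio 15.6, Fisher's exact p = 0.0946, two-sided). It passed, with the same count of 1, in calls on the same side in every direction (Fisher's exact p = 0.0373), strict genes (0.0171) and exonic SNPs (0.0317). The shared gene was the one at 4155070 to 4156370 on scaffold 1, with a Co deviation of 6.30 ± 0.41 (edgeR adjusted p = 3.26e-46) and Co maternal shares of 97.3%, 99.3% and 98.8%, with all of 334 reads maternal in direction 1 of pair 2 (down to 99.1% allowed). With at least 50 reads the Co adjusted p was 0.00176. With SNPs in annotated exons alone, the paternal overlap was 1 gene (odds ratio 10.1, Fisher's exact p = 0.130). With at least 10 reads the maternal overlap was 3 genes of 6 and 26 (odds ratio 47.5, Fisher's exact p = 0.000211), and with at least 50 reads it was 0. That minimum left out the shared gene, which had 46 and 35 reads in Cg pair 2, so its loss was fixed by the filter.

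**Figure D3:**
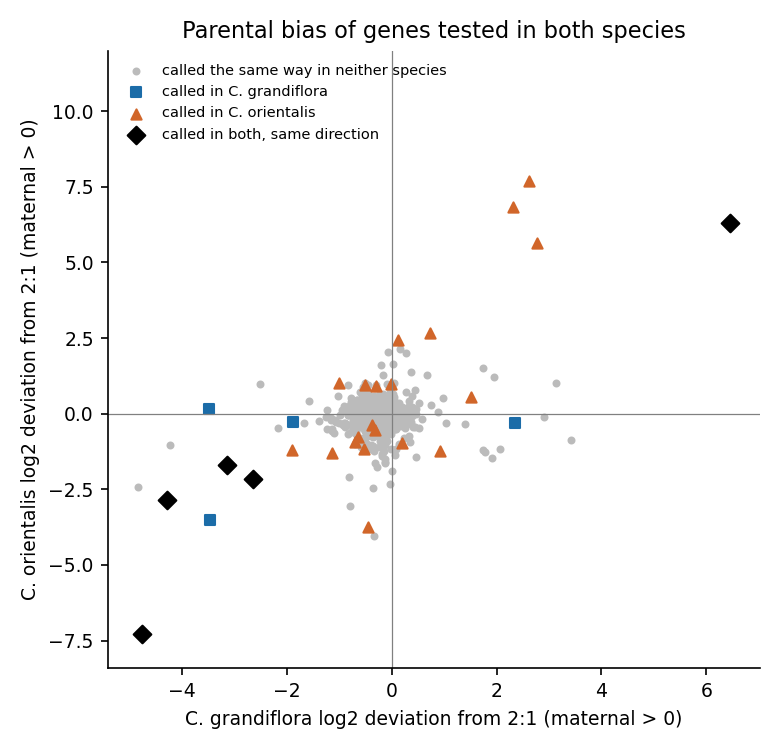
Log2 deviation from the 2 to 1 dosage in Cg (x axis) and Co (y axis) for the 584 genes tested in both species, positive where maternal. Black diamonds are the 5 genes called in both on the same side in every direction (1 maternal, 4 paternal), squares and triangles are such calls in Cg (4) or Co (20) not shared, and grey points are the other 555 genes.

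The last comparison tested directly whether parental bias differed between Cg and Co. It differed for 2 of the 584 genes (51 at an unadjusted p under 0.05), both more paternal in Co. The gene at 8879381 to 8883328 on scaffold 8, paternal in all directions of Co, had maternal shares of 78.4%, 32.8%, 24.1% and 89.3% in Cg. Its Cg deviation was -0.46 ± 0.25, and the difference, Co minus Cg, was -3.29 ± 0.35 (SE, n = 4 directions in 2 pairs per species, edgeR adjusted p = 0.0118). A gene on scaffold 8 (6227717 to 6228966, minus strand) was maternal in 3 Cg directions, at 94.3%, 92.7% and all of 39 reads (down to 92.3% allowed), and at 51.7% (34.4% to 68.6%) of 29 reads in direction 2 of pair 2. In Co its shares were 69.3%, 60.2%, 67.8% and 61.7%, near the dosage, and the difference was -3.01 ± 0.32 (edgeR adjusted p = 0.0118). The genes shared between species did not pass this test: the scaffold 7 gene differed by -2.94 ± 0.80 (edgeR adjusted p = 0.372) and the scaffold 1 gene by -0.29 ± 1.23 (adjusted p = 0.948). DESeq2 called 10 differences, 6 more paternal and 4 more maternal in Co, and the null at the median log ratio 7, 5 more paternal and 2 more maternal, so the direction was not one-sided there. The fit without the block called 0 (16 at an unadjusted p under 0.05). Leaving out direction 1 of Co pair 2 gave 9, and leaving out any other direction gave 0.

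The authors' deposited table of gene tests, is given here at an unadjusted p-value under 0.05 in both directions of 1 pair, a rule unlike the one above, so the counts were not compared. In the authors' deposited table for Cg pair 1 there were 590 genes maternal and 768 paternal in both directions, and 4438 that were maternal in one and paternal in the other. The authors' deposited tables gave 52, 804 and 1643 such genes for Cg pair 2, 35, 87 and 414 for Co pair 1, and 84, 65 and 647 for Co pair 2.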

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

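The tests of explanations in this part were chosen after the shares were seen, except that of SNPs of one accession only as a source of the low share in Cg pair 2. Of 21 sets of 4 directions examined, 7 had a direction far from the other 3. Chance gives about 1 in 20 for values that vary alike, a rate that does not apply to shares near 0% or 100% from unequal numbers of reads, as in most of the genes below.

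Direction 1 of Cg pair 2 had an exonic maternal share of 52.0%, far below the other 3 Cg directions. At SNPs read in both directions, over-counting of one accession's alleles would raise the opposite direction as much as it lowers this one. At well covered exonic SNPs (5164 SNPs with at least 20 reads in both directions) the median shares were 60.4% and 71.4%, and the mean of their log2 odds was 0.966, near the 1 of the dosage, but summed over the same SNPs the shares were 51.2% and 72.5% with a mean of 0.736 (0.696 to 0.774 over resampled genes), so the 2 measures disagree there. Over all reads the mean was 0.409, and 0.531 without SNPs of one accession only. Neither value decides on these causes, since only 56.6% of the SNPs of this pair were listed in both directions. SNPs read in 1 direction only do not follow that reasoning, and the removal of SNPs of one accession could not reach them. Tissue with a 1 to 1 dosage would lower well covered SNPs too, and their summed mean fell short of 1 by 0.264 against 0.591 for all reads (a ratio of 0.447, 0.394 to 0.501), so a part in direction 1 stays open; such tissue alone would not raise direction 2 above the dosage, and no biological explanation of a single direction was tested.

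Direction 1 of Co pair 1 had an exonic maternal share of 61.5%, against 66.4% to 66.8% in the other 3. Summed over exonic SNPs with at least 20 reads in both directions, the shares of Co pair 1 were 65.2% and 66.2%, so most of the gap was absent there. The Cg gene at 12789380 on scaffold 5 had a share of 82.8% in direction 1 of pair 2, where the others were wholly maternal. The Cg genes at 8166727 on scaffold 8 and 1940495 on scaffold 4 had shares of 10.8% and 33.3% in direction 2 of pair 2, above the other 3. The Co gene at 9766051 on scaffold 1 had a share of 81.7% in direction 1 of pair 1, below the others. The Cg gene at 6227717 on scaffold 8 had a share of 51.7% in direction 2 of pair 2, below the others.

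Parental bias differed between the species, by the interaction test, at 6227717 on scaffold 8 (Co minus Cg -3.01) and at 8879381 on scaffold 8 (-3.29). Of the 35 splits of the 8 directions into 4 and 4, 27 could be fitted, and because the accession terms absorb which direction of a pair is moved, they amount to 9 different fits, too few for a share under 0.05. The real split gave 2 genes, and 1 split, the real one, gave as many. The highest of the others was 1. At an unadjusted edgeR p under 0.05 the real split gave 51 genes and the highest of the others 56.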

How the results depend on the processing

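Exonic SNPs, SNPs listed in both directions, overlaps of same-side calls and the balance of calls were chosen after the data were seen. All calls rest on 4 directions per species, and the reads of Cg pair 2 and of Co set which genes could be tested. The count of 87 Cg genes stayed within 1.5 times with the median null, TMM, at least 10 reads, exonic SNPs, SNPs in both directions and removal of SNPs of one accession. The count of 137 Co genes did so with all of these, and also without a read filter. The binomial test was planned to count only genes on the same side in every direction, so its 380 Cg and 138 Co genes compare with 71 and 57, and without that requirement it called 461 maternal and 2033 paternal genes in Cg and 200 and 451 in Co. For the other settings the cause was not tested, except that a higher minimum, no minimum or a single SNP changed the genes tested (2180, 22614 and 1876 in Cg). For named genes, 143 values kept their side of the threshold and 85 did not, and none changed sign; 53 of the losses came from leaving out single directions, 12 with no accession term and 9 with no block.

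In Cg, calls became 143 with DESeq2, 284 with the null at 1 to 1, 34 with at least 50 reads, 246 without a filter and 3 with a single SNP. With the null at 1 to 1, 15.5% of Cg calls were paternal against 72.4%, and 1.70% of Co calls against 64.2%, as moving the null itself brings about. Same-side maternal Cg calls became 30, 49, 5, 40 and 1 under these settings in turn, 70 with the binomial test and 11 with exonic SNPs, from 18. Paternal ones became 25 with at least 50 reads, 106 without a filter, 2 with a single SNP and 310 with the binomial test, from 53. In Co, calls became 46 with DESeq2, 883 with the null at 1 to 1, 53 with at least 50 reads and 91 with a single SNP. Same-side maternal Co calls became 95 with the null at 1 to 1, 16 with at least 50 reads and 78 with the binomial test, from 30. Paternal ones became 7 with DESeq2, 4 with the null at 1 to 1, 9 with at least 50 reads, 14 with a single SNP, 60 with the binomial test and 14 with exonic SNPs, from 27. Strict counts became 24 in Cg and 9 in Co with at least 50 reads, and 28 in Co with shares of 0.80 and 0.45.

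Without the accession term 0 genes were called in either species, maternal, paternal or in all, with edgeR. Without the replicate block, 0 were called in Cg (108 at an unadjusted p under 0.05), 22 in Co (15 maternal and 4 paternal on the same side) and 0 for the species difference (16 at an unadjusted p under 0.05). Leaving out each direction gave 0 to 52 Cg calls (same-side maternal 0 to 12, paternal 0 to 33, strict 0 to 40), 0 to 44 Co calls (0 to 11, 0 to 3 and 0 to 11) and 0 to 9 differences. A pair left with 1 direction has no accession term, and the lone direction is assumed to vary like the others.

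The species difference became 10 genes with DESeq2, 7 with the median null and 1 with exonic SNPs, from 2. The odds ratio of the maternal overlap, 15.6, became 144.5 in strict genes (Fisher's exact p = 0.0171), 57.2 in same-side calls (p = 0.0373) and 47.5 with at least 10 reads (p = 0.000211). With at least 50 reads it was 0, where 1 and 6 genes shared none. That minimum left out the shared gene at 4155070 on scaffold 1, so its loss was fixed by the filter. The exonic odds ratio of the maternal overlap and the paternal one with at least 50 reads were infinite (Fisher's exact p = 0.0317 and 0.00412). The paternal overlap became 10.1 with exonic SNPs (Fisher's exact p = 0.130). The odds ratio of maternal to paternal same-side calls, Cg over Co, was 0.306 (Fisher's exact p = 0.00186), and 0.259 with a single SNP (p = 0.543), 0.364 in genes tested in both species (p = 0.427) and 0.684 over all calls (p = 0.242). These tests of overlap and balance took genes as independent. The fixed gene lists were not run, since the genes have no names.

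With the accession term removed, as other assignments of mother and father require, the real assignment gave 0 calls in each species, so all 8 of the 8 assignments gave as many, which a count of 0 makes certain. They are too few for a share under 0.05. The highest of the others was 1 in Cg, for an assignment that follows the accessions within each pair. At an unadjusted edgeR p under 0.05 that assignment had 255 Cg genes and the other one that follows the accessions had 216. The real one had 143, and the rest 5 to 153. In Co the highest of the others was 211, for the assignment that follows the accessions common to both pairs, which points to that structure of the samples. Without SNPs of one accession only, the real assignment called 26 Cg and 8 Co genes, and the highest of the others 0 and 78, the latter again following the accessions.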

Other observations

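The tests in this part were chosen after the values were seen, except that of the exonic SNPs of genes with SNPs of one accession only.

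Paternally biased genes of Cg lay near each other on the scaffolds. Of the 71 Cg genes on the same side in every direction, 16, all of them paternal, had another such gene within 5 tested genes, against 6.57 on average and 14 at the 97.5th percentile of 10000 permutations of the calls (permutation p = 0.00700). They included 3 genes on scaffold 4 between 1822859 and 1941686. In Co 17 of 57 genes had such a neighbour, against 10.4 on average (permutation p = 0.0659). Fewer genes were tested in Co, so the same window spanned more of a scaffold. Such neighbours lay up to 602163 bp apart in Co and up to 81868 bp in Cg, so the counts of the species do not compare. A candidate explanation is that parentally biased genes cluster, as a hypothesis from the data it was tested on. Shared regulation and related neighbouring genes that exchange reads were not tested. By scaffold, 16 of 490 tested genes on scaffold 4 of Cg were called (odds ratio 2.37, Fisher's exact p = 0.00624, adjusted p = 0.0874 over the scaffolds), which did not pass the correction.

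Calls on the same side in every direction were paternal more often in Cg (53 of 71, 74.6%) than in Co (27 of 57, 47.4%, Fisher's exact p = 0.00186). Among called genes passing the strict shares the percentages were 80.9% and 11.8% (Fisher's exact p = 7.61e-07). Over all calls they were 72.4% and 64.2% (Fisher's exact p = 0.242). The same-side rule at the dosage itself favours this, since of all tested genes on 1 side, called or not, 80.5% were on the paternal side in Cg and 38.7% in Co (Fisher's exact p = 7.19e-22). A shift of all Cg genes toward the father (median deviation -0.27, against -0.02 in Co) is argued against as the whole cause for the same-side calls. With the null and the sides at each direction's median, which removes such a shift, 39 of 59 Cg calls were paternal. In Co 28 of 64 were (Fisher's exact p = 0.0183). Over all calls with the null at the median, 65.7% of Cg and 64.9% of Co calls were paternal. The percentages were nearly equal there, so the argument covers same-side calls only. Without SNPs of one accession only, Fisher's exact p of the same-side calls was 0.00149, which argues against those with reads in both directions. SNPs read in 1 direction only could not be removed. Different genes were tested in the species, and among those tested in both (7 of 9 and 14 of 25 paternal, Fisher's exact p = 0.427) the counts were too few, so this cannot be told apart from a difference between the species. The species themselves, the depth and the number of accessions, which differ together, stay open and untested, as does maternal tissue in the samples. So does the more lenient test in Co, where paternal calls had a median deviation of -1.21, against -3.02 in Cg. Fisher's exact test took genes as independent, although 16 of the Cg calls, all paternal, had another such call nearby. Its p-values therefore compare lists of called genes and do not rest on replicates of the species.

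SNPs outside annotated exons often carried reads of one accession only. Of those with at least 20 reads in both directions, 32.5% and 55.2% in Cg and 49.6% and 47.3% in Co had over 95% of reads from the same accession in both, against 2.26%, 11.1%, 3.03% and 4.65% of exonic SNPs. If the gene were expressed from that accession's allele alone, its exonic SNPs would show it too. They did so in 10 of 1412 genes (0.708%), counted in each pair and summed, which argues against this explanation. Most of the genes came from Cg pair 1. By pair the counts were 7 of 1255 and 0 of 65 in Cg, and 0 of 17 and 3 of 75 in Co. Positions wrongly taken for SNPs, and transcripts other than the annotated one, stay open and were not tested.

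Accession differences were called by edgeR in 164 and 352 Cg genes (pairs 1 and 2) and in 285 and 263 Co genes. Across the 584 genes tested in both species, which are not independent replicates, deviations correlated with r = 0.47 and rho = 0.13.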
